A study of Mus musculus with 9 samples.

How the data were processed

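Single-cell RNA-seq was available for 9 libraries from mouse femurs, with 1 sham and 2 grafted libraries on each of days 1, 7 and 14. Per the file headers, each matrix held raw counts of unique molecular identifiers (UMIs, tags that let each captured RNA molecule be counted once) per gene and barcode, written by Cell Ranger 4, while Cell Ranger 8.0.0 is named per the submitters' processing notes. The genome build and annotation release behind the counts were not given in the sources used here, so no coordinates are printed. The deposited counts covered every barcode, empty droplets included, and no cell calls, cell types or normalized values were used. The gene table also held 3 GFP transcripts, of which EGFP had UMIs and GFPuv and pBad_pGFPuv had 0 in retained cells. Per the labels' protocols, flushed marrow and enzyme digests of crushed bone were sorted for DAPI-negative cells, whereas the series design names periosteum. The protocol also names a kit for bulk RNA. The labels do not say which holds, and both the tissue and the sort can set the shares of cell classes.

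A barcode was kept as a cell with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. A barcode below 2000 UMIs also had to differ from the ambient profile, the summed counts of barcodes with 100 UMIs or fewer, by a Monte Carlo multinomial test (10000 simulations, Benjamini-Hochberg adjusted p of 0.01). Doublets were scored with scrublet as provided in scanpy 1.11.5. Its automatic threshold marked 0 barcodes in 2 of the day 7 libraries, so the highest scores were removed in every library at a rate of 0.8% per 1000 cells, which took out 3.07% to 7.40% of the barcodes of a library. That rule was chosen after seeing the scores. Counts were scaled to the same total per cell and logged, 2000 variable genes were reduced to 30 principal components, and cells were joined to 15 neighbours and grouped by the Leiden algorithm at resolution 1 (leidenalg 0.10.2) over the 9 libraries together. EGFP, sex-linked transcripts and antigen receptor segments were kept out of the variable genes. No batch correction was applied.

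The 33 clusters were named by markers of 20 classes fixed before the data were examined, and the rule that turned markers into names was set after the clusters had been seen. A cluster took the name with the most markers among its 10 leading genes and, on a tie, the name whose markers were higher on average, which decided cluster 13 (4 markers each of monocyte and macrophage and of dendritic cells). It stayed unnamed where markers of another class were higher on average by more than 1 on the log2 scale, or where its UMIs were under 1/3 of the library medians with none of the markers leading. Clusters 14, 21 and 27 stayed unnamed and were tested by number. Cluster 21 had 4 leading markers of dendritic and 3 of B cells, with those of B cells higher on average. Shares were taken over retained cells that were not erythroid-like, since red cell lysis can vary between libraries.

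Shares of 13 classes and unnamed clusters, and the share of cells with EGFP, were compared by a two-sided exact permutation test within days (27 arrangements, so the smallest p it can give is 0.0370). For gene tests, counts were summed per library and class, and libraries with under 20 cells of a class were left out. Genes passing filterByExpr were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood F test, Benjamini-Hochberg threshold of 0.05). Grafted against sham was fitted with day and treatment, the contrasts between grafted days with 1 mean per day and treatment, and the difference of the graft effect between days with the day by treatment terms. Every library of a class entered each fit, so a group of 1 library was assumed to vary like the groups of 2. Log2 CPM (counts scaled to library size) were computed with a prior count of 2. Values are log2 fold changes with a standard error (SE) unless another unit is named, the SE being the fold over the square root of the F statistic.

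Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01 and again with an estimated correlation, wherever at least 5 members were measured. Benjamini-Hochberg adjustment ran over the lists of a comparison. The 25 lists were inflammatory cytokines and chemokines, interferon response, hypoxia and glycolysis, osteoblast and mineralization, cartilage, fibrous matrix and matrix remodelling, marrow stromal niche, angiogenic endothelium, endothelial adhesion and inflammation, marrow sinusoid and arteriole, cell cycle, osteoclast, lipid-associated (Trem2) macrophage, resident macrophage, alternative activation, antigen presentation class II, neutrophil primary granules, neutrophil secondary and tertiary granules, mature and activated neutrophil, dissociation and immediate early, RNA of neutrophils, erythroid cells, B cells and skeletal muscle as markers of other cell types, and mitochondrial transcripts as a sign of RNA quality. Of these, Spp1, Vcam1, Apoe, Mrc1 and other genes stand in more than 1 list.

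Genes were named by a rule fixed before the data were examined. Among genes past the threshold with a mean log2 CPM of at least 5, the 6 with the largest rise and the 6 with the largest fall were named. For grafted against sham, each also had to differ from the sham library of its day in the same direction in all 6 grafted libraries. For day contrasts, the libraries of both days could not overlap. Predicted gene models, antigen receptor segments, sex-linked transcripts and markers of other cell types were left out of that part. From each list called by camera, the 4 members with the smallest p were named, called or not, and other members of the lists could be given as values. For the difference of the graft effect between days, the 6 genes with the smallest p were named.

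The tests were run on simulated counts with the real means and library sizes and 200 changed genes. Apart from these changes each gene had the same mean in every library, so day effects were not simulated. The rates below need not hold for the data, where more genes differed. For grafted against sham in neutrophil-like cells, 70% of genes changed by a log2 fold of 1 and 98% of those changed by 2 were recovered, with 9 false calls among 13964 genes. For day 7 against day 1 these were 73%, 90% and 17. In monocyte and macrophage-like cells, 71% and 92% were recovered for grafted against sham with 9 false calls among 13907 genes, and 55% and 83% for day 7 against day 1 with 19.

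The alternatives tried were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no filter on low counts, a minimum of 1000 UMIs, a mitochondrial maximum of 5%, doublets kept, resolutions 0.5 and 2, all retained cells as denominator, a replicate block, and leaving out each library in turn. Added after seeing the data were fits without cells holding EGFP, without clusters 26, 27 or 29, within clusters 11 and 12, 22 or 13 alone, with a minimum of 15 cells, and shares with cluster 21 counted as B cell-like or cluster 13 as dendritic-like. The scalings moved the median log2 fold of all genes by between -0.03 and 0.02. For shares of cells with EGFP across depths, each cell was thinned to 2000 UMIs. Intervals are exact binomial (Clopper-Pearson) at 95% and, like the limits of 3 counts given for shares of 0, cover counting error only. Gene spans for 1 check came from a GENCODE mouse annotation that matched 99.9% of genes and may differ from the one used for counting. Comparisons of grafted with sham and of day 7 with day 1 in mesenchymal-like and endothelial-like cells had too few libraries with 20 cells and were left out.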

Results

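Single-cell RNA-seq libraries came from femurs of mice given a bone graft and from sham-operated femurs, collected 1, 7 and 14 days after surgery. Graft donors carried a GFP transgene driven by the ubiquitin C promoter, which is active in most cell types, so that an EGFP transcript can mark cells that came with the graft, although free RNA can carry it too. Each day had 1 sham and 2 grafted libraries. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. The sham libraries of days 1, 7 and 14 held 73981719, 133992973 and 78422590 UMIs in all, of which 3724, 7423 and 5606 barcodes were kept as cells. The grafted replicates held 104883119 and 116193195 UMIs on day 1 (6403 and 7932 cells), 128473240 and 124987236 on day 7 (8566 and 6556 cells), and 125953563 and 123050351 on day 14 (6781 and 6999 cells). Median UMIs per cell ran from 7099 to 10852 per library. The median mitochondrial share was 0.551% to 0.624% in the 3 libraries of day 7 and 1.14% to 2.69% in the others, so day and a possible batch cannot be separated. Replicates of a grafted group correlated across genes at r = 0.991 or more in neutrophil-like and 0.986 or more in monocyte and macrophage-like cells, where genes are not independent replicates.

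The first comparison asked which cell classes were more or less frequent in grafted than in sham femurs of the same day. Neutrophil-like cells were the most frequent class, with a mean of 53.9% of cells in grafted and 55.8% in sham libraries (log2 odds difference -0.12, exact p = 0.815, higher in 3 of 6 grafted libraries). B cell-like cells were at 18.1% in grafted and 11.8% in sham libraries (log2 odds difference 0.94), endothelial-like cells, which line vessels, at 0.254% and 0.0682% (1.49), and each was higher in 6 of 6 grafted libraries. Endothelial-like cells numbered only 2, 4 and 5 in the sham libraries of days 1, 7 and 14, and 6 and 5 in the grafted day 1 replicates. Dendritic-like cells were at 1.54% and 2.97% (-0.97) and granulocyte-monocyte progenitor-like cells at 2.44% and 4.33% (-0.76). Basophil and mast-like cells were at 0.705% and 0.870% (-0.32), and each of these classes was lower in 6 of 6. All dendritic-like cells lay in cluster 19, led by Ly6d, Siglech and Cox6a2. Cluster 13, led by the class II genes Cd74 and H2-Aa and not counted as dendritic-like, was at 1.96% and 1.17% (0.66, higher in 6 of 6, exact p = 0.0741). B cell-like and dendritic-like cells depend on where 2 clusters are counted. With cluster 21, which B cell markers would also fit, B cell-like cells were at 22.2% and 17.8% (0.32, higher in 5 of 6, exact p = 0.185). With cluster 13, in which markers of dendritic and of monocyte and macrophage-like cells tie, dendritic-like cells were at 3.50% and 4.13% (-0.31, lower in 5 of 6, exact p = 0.185). By the naming rule, for these 5 classes the two-sided exact permutation test gave p = 0.0370, the smallest that 27 arrangements can give, and adjusted p = 0.0802 over the 13 classes tested, so none passed the correction. Mesenchymal-like cells, which include bone-forming and connective tissue cells, were at 0.893% and 0.0610% (2.95, higher in 5 of 6, exact p = 0.0741). They numbered 240 and 107 cells in the day 7 grafted replicates (2.26% ± 0.846, SD, n = 2) and 1 cell in the sham library of day 7. Without the sham library of day 7 or day 1 their log2 odds difference was 1.05 (exact p = 0.333) and 4.48. Monocyte and macrophage-like cells were at 11.7% and 11.3% (0.06, exact p = 0.519; -0.07 without cluster 13), T and NK-like cells at 3.79% and 4.58% (-0.32, exact p = 0.444) and plasma-like cells at 0.151% and 0.395% (-1.47, exact p = 0.222; -0.57 without the sham library of day 1). The sign for neutrophil-like cells turned without the sham library of day 14 (0.08) or grafted day 14 replicate 2 (0.03), and that for T and NK-like cells without the sham library of day 1 (0.07). With edgeR on cell numbers, B cell-like (adjusted p = 0.0227), dendritic-like (0.00145), endothelial-like (0.0152) and granulocyte-monocyte progenitor-like cells (0.0152) passed. B cell-like cells with cluster 21 (0.253) and dendritic-like cells with cluster 13 (0.312) did not.

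Among clusters without a name, cluster 14 was at 1.37% of cells in grafted and 1.81% in sham libraries (log2 odds difference -0.41, exact p = 0.185). Cluster 21, led by B cell and antigen presentation genes, was at 4.09% and 6.03% (-0.43, exact p = 0.407), and its sign turned without the sham library of day 7 (0.04). Cluster 27 was at 0.997% in grafted libraries (5.81, higher in 6 of 6, exact p = 0.0370, adjusted p = 0.0802) and held 0 cells in each sham library. Its UMI counts per gene followed the length of the gene (Spearman rho 0.888 across genes, which are not independent replicates).

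**Figure D1:**
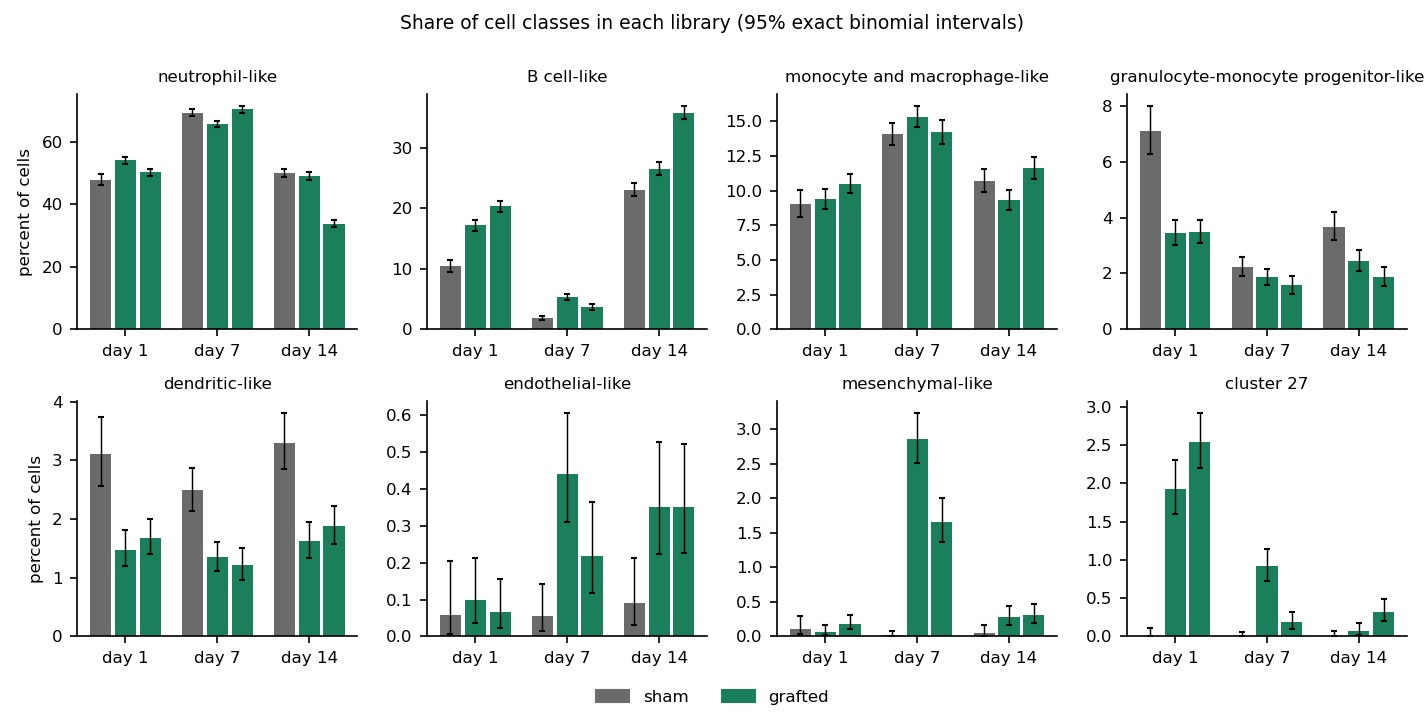
Share of cells that are not erythroid-like (%, one panel per class, axes starting at 0) in each library on days 1, 7 and 14, with 1 bar per sham or grafted library and whiskers giving exact 95% binomial intervals. Mesenchymal-like cells stand highest in the day 7 grafted libraries (2.86% and 1.66%). B cell-like cells, counted without cluster 21, lie higher in all 6 grafted libraries than in the sham library of their day.

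EGFP was carried by the graft donors. No EGFP UMI was found in the 3 sham libraries (0 of 3724, 7423 and 5606 cells on days 1, 7 and 14, which allows shares of up to 0.0806%, 0.0404% and 0.0535%). In grafted libraries 2.96% ± 0.194 (SD, n = 2) of cells had EGFP on day 1, 2.70% ± 0.0714 on day 7 and 0.276% ± 0.0267 on day 14 (grafted against sham within days, log2 odds difference 7.17, exact p = 0.0370, the smallest possible). On day 1, 92.7% of the 427 cells with EGFP were neutrophil-like. In these, 396 of 7101 cells (5.58%) had EGFP on day 1, 232 of 10048 (2.31%) on day 7 and 13 of 5522 (0.235%) on day 14. After thinning to 2000 UMIs the shares were 4.42%, 1.81% and 0.219% of 7011, 9867 and 5475 cells, leaving out shallower ones. These values pool both replicates of a day. On day 14 the thinned cells with EGFP were 12 of 3183 in replicate 1 and 0 of 2292 in replicate 2. B cell-like cells, which serve as the level of free RNA, had 0.233%, 0.876% and 0.0479% before thinning and 4 of 2536, 0 of 673 and 1 of 4147 cells after it. Barcodes with 100 UMIs or fewer, which hold free RNA, had EGFP at 21.5 and 16.5 CPM on day 1, 37.7 and 28.5 on day 7, and 5.44 and 4.23 on day 14, against 20.6 and 17.4, 51.4 and 43.6, and 5.59 and 5.24 CPM in cells. Median UMIs per library were 3927 to 12952 in B cell-like and 6455 to 10376.5 in neutrophil-like cells of grafted libraries. Cluster 26, a small neutrophil-like cluster formed without EGFP among its variable genes, had EGFP in 149 of 161 cells (92.5%) on day 1. It had EGFP in 0 of 21 cells on day 7 and in 0 of 2 cells on day 14.

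On day 7, EGFP was found in 70 of 347 mesenchymal-like cells (20.2%), in 9 of 51 endothelial-like cells (17.6%) and in 71 of 2201 monocyte and macrophage-like cells (3.23%). On day 14 these were 9 of 39 (23.1%), 7 of 47 (14.9%) and 4 of 1403 cells (0.285%). After thinning, 42 of 239 and 16 of 52 mesenchymal-like cells of the day 7 replicates had EGFP (17.6% and 30.8%, exact intervals 12.97% to 23.0% and 18.7% to 45.1%), with 1 and 55 shallower cells left out. In day 14 replicate 1, 1 of 16 thinned mesenchymal-like cells had EGFP, and in replicate 2, 4 of 21. Thinned endothelial-like cells with EGFP were 5 of 37 and 3 of 14 in the day 7 replicates and 1 of 23 and 5 of 24 on day 14. Thinned monocyte and macrophage-like cells were at 0.467%, 1.86% and 0.221% on days 1, 7 and 14, with 3 of 601 and 0 of 757 cells in the day 14 replicates. Median UMIs of mesenchymal-like cells were 35884.5 and 1898 in the day 7 replicates, and thinned B cell-like cells of that day had 0 of 673, with an exact upper limit of 0.547%.

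**Figure D2:**
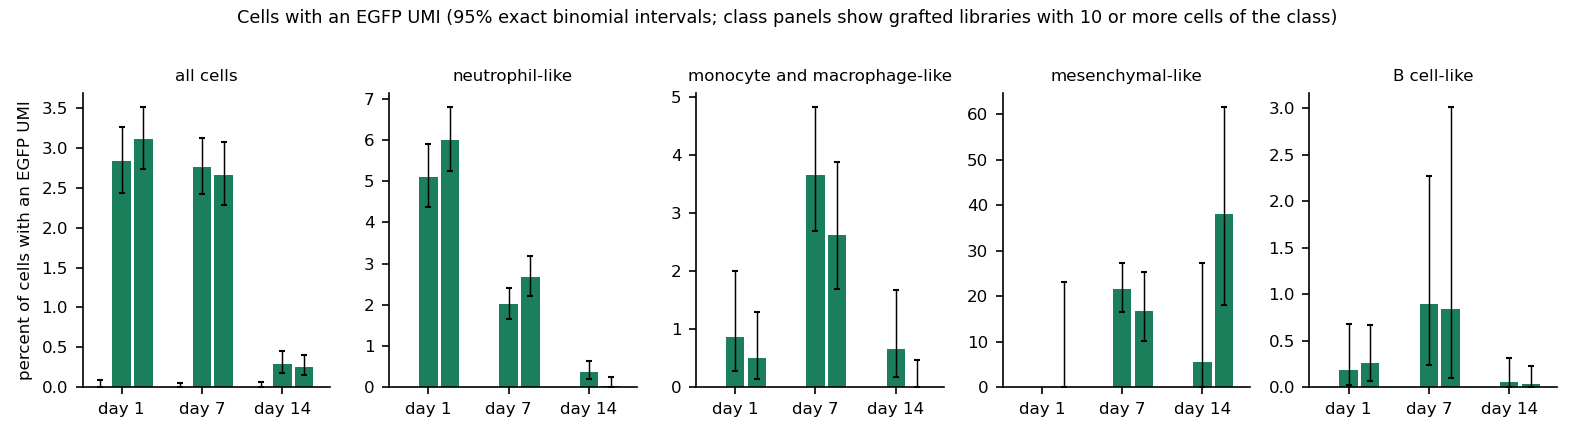
Share of cells with at least 1 EGFP UMI (%, y axis from 0) in each library against day, for all cells and for 4 classes, with 1 bar per library and whiskers giving exact 95% binomial intervals. The class panels show grafted libraries only. Sham libraries stay at 0, grafted day 14 libraries lie at 0.295% and 0.257% of all cells, and grafted day 1 and day 7 libraries lie between 2.65% and 3.10%.

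The question in neutrophil-like cells was how expression in grafted femurs differed from sham femurs of the same day. Egr1 (ENSMUSG00000038418), an immediate early transcription factor, rose by a log2 fold of 2.75 ± 0.12 (SE; edgeR adjusted p = 1.98e-07; 6 grafted and 3 sham libraries). The chemokines Cxcl3 and Ccl4 rose by 2.31 ± 0.25 and 2.26 ± 0.26 (adjusted p = 0.000158 and 0.000261), Ptgs2, the inducible cyclooxygenase, by 1.76 ± 0.10 (adjusted p = 1.29e-06), Spp1, which encodes osteopontin, by 2.05 ± 0.21, and the transcriptional repressor Tgif1 by 1.83 ± 0.22. Ltb, a cytokine of the tumor necrosis factor family, fell (-1.45 ± 0.19), as did the interferon-induced Ifi27l2a (-0.94 ± 0.10), the granule proteases Prtn3 and Elane (-0.81 ± 0.14 and -0.78 ± 0.14), Cdh23 (-0.79 ± 0.13) and Tnfaip8l2 (-0.78 ± 0.11). As the naming rule required, each of these 12 genes differed from the sham library of its day in the same direction in all 6 grafted libraries. In all, 2768 of 13964 genes passed the test, 1404 higher and 1364 lower, and 533 rose and 30 fell by a log2 fold of at least 1. The count was 1724, 1769 and 1705 without the sham library of day 1, 7 or 14, and 1630 without grafted day 14 replicate 1. On day 1 most neutrophil-like cells lay in clusters 1 and 2 in grafted libraries (30.6% and 37.2% in replicate 1) and in clusters 2 and 3 in the sham library (38.8% and 27.1%), and on days 7 and 14 cluster 10 held 40.6% to 46.5% in grafted libraries while clusters 4 and 5 held 29.2% and 25.2% of the day 7 sham cells. Without cells holding EGFP 2601 genes passed.

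Groups of neutrophil genes moved together between grafted and sham femurs. Of 19 measured inflammatory cytokines and chemokines, 14 rose and none fell (15 passed when adjusted over the list alone), among them Csf3, the granulocyte growth factor (2.54 ± 0.26), and Cxcl2 (1.51 ± 0.16). camera called the list at adjusted p = 1.17e-08 (adjusted p = 0.3001 with an estimated correlation). Of 17 genes of mature and activated neutrophils 10 rose (11 adjusted over the list alone), with Cd14, the endotoxin co-receptor, at 0.97 ± 0.15 (camera adjusted p = 7.37e-05, and adjusted p = 0.401 with an estimated correlation). Of 18 dissociation and immediate early genes 9 rose and 1 fell (11 adjusted over the list alone), with Dusp1, a phosphatase induced by stress, at 1.24 ± 0.11 and Atf3 at 1.10 ± 0.14 (adjusted p = 7.31e-05, and adjusted p = 0.304 with an estimated correlation). Of 10 alternative activation genes 4 rose (9 adjusted over the list alone), including the cytokine signalling inhibitor Socs3 at 1.39 ± 0.13 and Pdcd1lg2 at 0.92 ± 0.13 (adjusted p = 0.00481, and adjusted p = 0.3001 with an estimated correlation). Of 10 primary granule genes 9 fell and all 10 passed when adjusted over the list alone, among them Cebpe, a transcription factor of granulocyte maturation (-0.68 ± 0.07), and Ms4a3 (-0.52 ± 0.08; adjusted p = 7.31e-05, and adjusted p = 0.3001 with an estimated correlation). Of 15 secondary and tertiary granule genes 5 fell (7 adjusted over the list alone), with Anxa1 at -0.50 ± 0.10 and Hp at -0.54 ± 0.13 (adjusted p = 7.37e-05, and adjusted p = 0.3001 with an estimated correlation). Of 23 cell cycle genes 13 fell (14 adjusted over the list alone), with Birc5 at -0.56 ± 0.09, Ccnb2 at -0.53 ± 0.09 and Aurka at -0.52 ± 0.09 (adjusted p = 7.31e-05, and adjusted p = 0.456 with an estimated correlation). Of 16 interferon response genes 7 fell (10 adjusted over the list alone), with Rtp4 at -0.53 ± 0.11, Stat1 at -0.43 ± 0.09 and Irf7 at -0.41 ± 0.10 (adjusted p = 0.000112, and adjusted p = 0.401 with an estimated correlation).

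Genes of bone, cartilage and fibrous matrix were also higher in neutrophil-like cells of grafted libraries, at low counts. Of 12 osteoblast genes 7 rose (7 adjusted over the list alone), with Runx2, the osteoblast transcription factor, at 0.47 ± 0.11. Of 7 cartilage genes 5 rose (6 adjusted over the list alone). Of 21 fibrous matrix genes 15 rose (19 adjusted over the list alone). camera called these lists at adjusted p = 0.000371, 0.00424 and 4.85e-06 (adjusted p = 0.3001, 0.3001 and 0.401 with an estimated correlation). Col3a1, a fibrillar collagen, had 995 counts over the grafted and 2 over the sham libraries, Col2a1, the cartilage collagen, 198 and 3, Timp1 156 and 5, and the cartilage proteoglycan Acan 68 and 0. On day 7 the 15 fibrous matrix genes that rose held 35.2 UMIs per 100 neutrophil-like cells of grafted libraries. They held 59.3 per 100 B cell-like cells and 38.4 per 100 T and NK-like cells. Osteoblast and cartilage genes were not counted there. Of 8 neutrophil RNA genes, used elsewhere as a marker of free RNA, 2 fell (6 adjusted over the list alone), with Lcn2 at -0.37 ± 0.12 and Mmp8 at -0.32 ± 0.10 (adjusted p = 0.00127, and adjusted p = 0.376 with an estimated correlation). Of 8 mitochondrial transcripts 1 rose, mt-Nd1 at 0.34 ± 0.09 (1 adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.600 with an estimated correlation). The other 12 lists were not called in this comparison (camera adjusted p = 0.0790 to 0.726): hypoxia and glycolysis (5 of 18 rose, 2 fell), marrow stromal niche (3 of 9 fell), angiogenic endothelium (2 of 11 rose), endothelial adhesion and inflammation (2 of 10 rose, 2 fell), marrow sinusoid and arteriole (2 of 10 fell), osteoclast (3 of 9 rose, 1 fell), lipid-associated macrophage (6 of 14 rose, 1 fell), resident macrophage (2 of 10 fell), antigen presentation class II (2 of 10 rose), B cell RNA (1 of 8 rose), and erythroid and skeletal muscle RNA (no member passed).

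**Figure D3:**
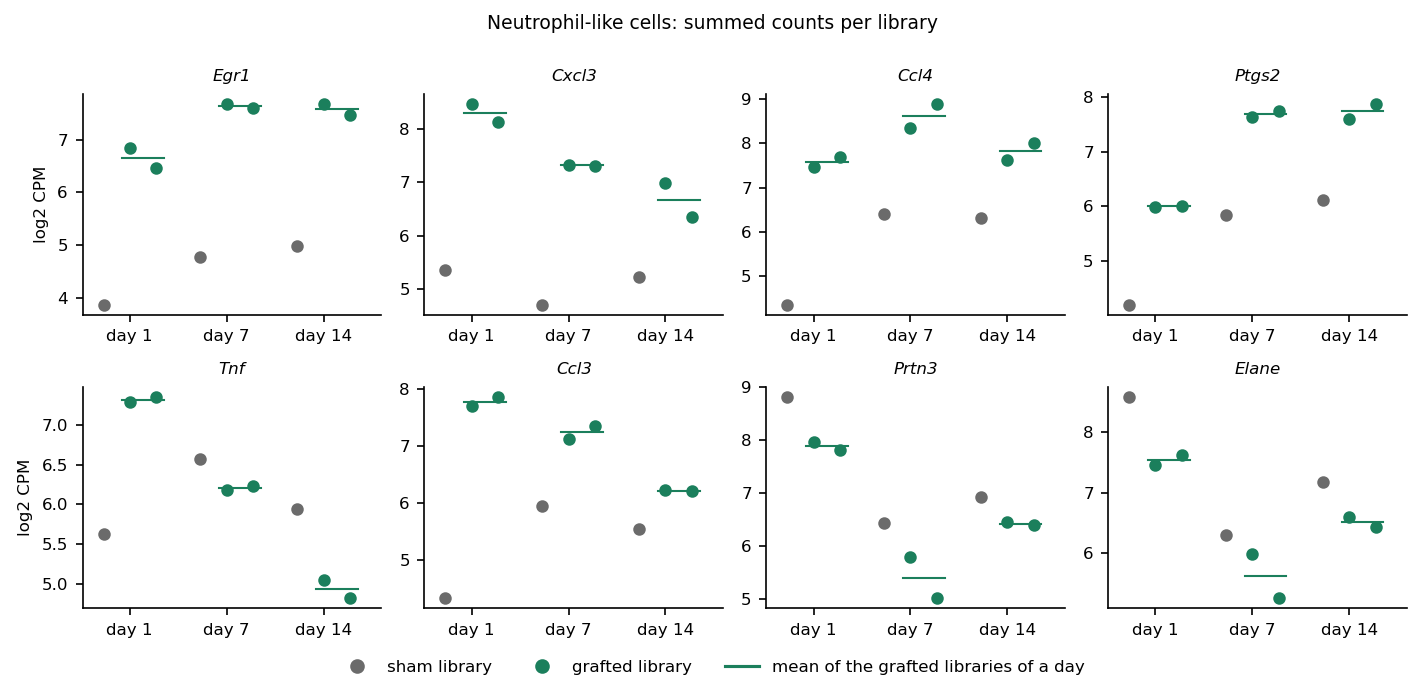
Log2 CPM of 8 genes in neutrophil-like cells (y axis, one panel per gene) against day, with 1 point per library for sham and grafted femurs. Egr1, Cxcl3, Ccl4, Ptgs2 and Ccl3 lie higher in all 6 grafted libraries than in the sham library of their day, Prtn3 and Elane lie lower in all 6, and Tnf lies higher on day 1 (1.70) and lower on day 14 (-1.002) on average.

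For 81 genes in neutrophil-like cells the graft effect itself differed between days (edgeR day by treatment terms, 9 libraries). Tnf (ENSMUSG00000024401), the cytokine itself, was higher in grafted than sham femurs by a log2 difference of 1.70 on day 1 and lower by -0.37 and -1.002 on days 7 and 14 (adjusted p = 0.00024). The chemokine Ccl3 differed by 3.44, 1.29 and 0.67 on days 1, 7 and 14 (adjusted p = 0.000337). Tnfaip3 and Tnip1, inhibitors of NF-kappa B signalling, differed by 1.89, 0.41 and -0.70 and by 1.05, -0.05 and -0.84 (adjusted p = 0.000952 and 0.00489). Spata13 (1.33, 0.15 and -0.61) and Gpr84, a receptor for medium-chain fatty acids (1.76, 0.48 and -0.36), completed the 6 genes with the smallest p (adjusted p = 0.00243 and 0.00584). Values within a day rest on 1 sham library. Without the sham library of day 1 the count was 2 and none of these 6 genes passed. It was 51 without grafted day 1 replicate 2, 47 without the sham library of day 14, and 36 and 31 without the grafted day 14 replicates, and was 124 without the sham library of day 7 and 211 and 251 without the grafted day 7 replicates.

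Between grafted days, the question was how neutrophil-like cells changed over time. From day 1 to day 7, Jaml, an adhesion molecule of leukocytes, rose by 3.56 ± 0.13 (adjusted p = 7.14e-08; 2 and 2 libraries), Cdk8 by 3.17 ± 0.47, Mrps28 by 3.17 ± 0.22, Pde7b by 3.15 ± 0.20, the immediate early gene Fos by 2.77 ± 0.14 and Slc25a33 by 2.73 ± 0.18. Prtn3 and Elane, proteases of primary granules, fell (-2.43 ± 0.20 and -1.88 ± 0.19), as did the chaperone-like Manf (-2.08 ± 0.12), Dbi (-1.49 ± 0.12), the ribosomal gene Rps2 (-1.47 ± 0.12) and Arhgef3 (-1.45 ± 0.11). In all, 5777 of 13964 genes passed, 2991 higher and 2786 lower. Of these, 94.4% differed in the same direction between the sham libraries of these days, a contrast that was not tested. The median ratio of the sham to the grafted difference was 0.864, so changes of similar size were seen without a graft. Most neutrophil-like cells of grafted libraries lay in clusters 1 and 2 on day 1 and in clusters 10 and 4 on day 7 (43.2% and 21.9% in replicate 1). Cluster 8, led by Camp, Ngp and Chil3 with Elane and Fcnb among its 10 leading genes, held 8.77% and 10.55% of the class in the day 1 replicates and 4.61% and 4.01% on day 7, and its part in the cell cycle and primary granule lists was not tested.

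Cell cycle genes fell throughout from day 1 to day 7 in neutrophil-like cells: 23 of 23 fell (23 adjusted over the list alone), with Ccnb1 at -1.43 ± 0.14, Plk1 at -1.38 ± 0.14 and Tubb5 at -1.22 ± 0.12 (camera adjusted p = 2.77e-09). Of 10 primary granule genes 9 fell and 1 rose (10 adjusted over the list alone), with Mpo, myeloperoxidase, at -1.71 ± 0.15 and Ms4a3 at -1.36 ± 0.10 (adjusted p = 0.000334). Both lists had adjusted p = 0.377 with an estimated correlation. Of 18 hypoxia and glycolysis genes 10 fell and 3 rose (17 adjusted over the list alone), with the cytokine Mif at -2.26 ± 0.13, Bnip3 at -1.80 ± 0.15 and Tpi1 at -1.17 ± 0.11 (adjusted p = 0.00586, and adjusted p = 0.491 with an estimated correlation). Of 19 inflammatory genes 13 rose and 4 fell (17 adjusted over the list alone), with the inflammasome sensor Nlrp3 at 1.94 ± 0.13, Il1b at 1.91 ± 0.14 and Ptgs2 at 1.69 ± 0.12, while Tnf fell (-1.11 ± 0.11; list adjusted p = 0.00354). Of 17 mature and activated neutrophil genes 13 rose and 2 fell (16 adjusted over the list alone), with Clec4d at 1.81 ± 0.17 and the decoy receptor Il1r2 at 1.44 ± 0.13 (adjusted p = 0.000334). Of 16 interferon response genes 9 rose (9 adjusted over the list alone), with Rsad2 at 2.05 ± 0.14 and Rtp4 at 1.91 ± 0.15 (adjusted p = 0.000423). Of 18 dissociation and immediate early genes 12 rose and 2 fell (14 adjusted over the list alone), with Atf3 at 2.32 ± 0.13 and Dusp1 at 2.15 ± 0.12 (adjusted p = 0.000468). These 4 lists had adjusted p = 0.377 with an estimated correlation.

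Matrix and macrophage transcripts rose alongside in these cells. Of 21 fibrous matrix genes 18 rose (19 adjusted over the list alone; adjusted p = 6.67e-09), with Fn1, fibronectin, at 3.14 ± 0.28. Of 12 osteoblast genes 9 rose (9 adjusted over the list alone; adjusted p = 0.00157), with Col1a1 at 3.15 ± 0.31. Of 11 angiogenic endothelium genes 6 rose (6 adjusted over the list alone; adjusted p = 0.0165), with Angpt2 at 2.71 ± 0.37. Of 10 class II antigen presentation genes 7 rose (7 adjusted over the list alone; adjusted p = 0.000423), with H2-Eb1 at 3.37 ± 0.27 and Cd74 at 2.07 ± 0.23, and of 8 B cell RNA genes 6 rose (6 adjusted over the list alone; adjusted p = 0.00586), with Ighm at 1.53 ± 0.17. These 5 lists had adjusted p = 0.377 with an estimated correlation. Of 14 lipid-associated macrophage genes 6 rose (6 adjusted over the list alone), with the lipid carrier Apoe at 4.49 ± 0.19 (adjusted p = 0.0458, and adjusted p = 0.410 with an estimated correlation). UMIs per 100 cells of the 15 fibrous matrix genes higher in grafted than sham neutrophil-like cells went from 3.21 to 35.2 in neutrophil-like cells. In B cell-like cells they went from 7.29 to 59.3 between these days. The other 12 lists were not called (adjusted p = 0.0610 to 0.964).

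Day 14 was compared with day 7 in neutrophil-like cells in the same way. The protease inhibitors Cstdc5 and Stfa1 fell (-2.74 ± 0.34 and -2.22 ± 0.19), as did Cdk8 (-2.04 ± 0.45), Il31ra (-1.78 ± 0.24), Tnfaip3 (-1.68 ± 0.12) and Nfkbia (-1.61 ± 0.12), both inhibitors of NF-kappa B. The histone genes Hist1h1b and Hist1h3c rose by 1.15 ± 0.13 and 1.11 ± 0.16, Prtn3 by 0.97 ± 0.19, Top2a and Kif11, genes of dividing cells, by 0.91 ± 0.13 and 0.88 ± 0.14, and Fcnb by 0.88 ± 0.11 (adjusted p between 8.27e-05 and 0.0106 for these 12 genes, 2 and 2 libraries). In all, 2416 genes passed, 955 higher and 1461 lower, and 80.3% of these differed in the same direction between the sham libraries of these days. The count was 1414 without grafted day 7 replicate 2, and 724 and 414 without grafted day 14 replicate 1 or 2. Cluster 8 held 8.34% and 9.70% of the class in the day 14 replicates, against 4.61% and 4.01% on day 7, and its part in the lists below was not tested.

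Of 19 inflammatory genes 17 fell from day 7 to day 14 (17 adjusted over the list alone), with Tnf at -1.26 ± 0.11, Nlrp3 at -1.11 ± 0.13 and Ccl3 at -1.02 ± 0.11 (adjusted p = 4.68e-10). Of 17 mature and activated neutrophil genes 12 fell (13 adjusted over the list alone), with Cxcl2 at -1.19 ± 0.15 and Il1b at -0.99 ± 0.14 (adjusted p = 5.55e-06). Of 23 cell cycle genes 21 rose (21 adjusted over the list alone), with Mki67, the proliferation antigen, at 0.77 ± 0.12 (adjusted p = 5.50e-11). Of 10 primary granule genes 5 rose (7 adjusted over the list alone), with Mpo at 0.81 ± 0.15 and Ms4a3 at 0.64 ± 0.10 (adjusted p = 0.00457). Of 18 dissociation and immediate early genes 9 fell (10 adjusted over the list alone), with Ier3 at -1.28 ± 0.19 and Klf2 at -0.79 ± 0.10 (adjusted p = 0.000434). These 5 lists had adjusted p = 0.287 with an estimated correlation. Of 18 hypoxia and glycolysis genes 9 fell (10 adjusted over the list alone; adjusted p = 0.000251), with Hk2 at -0.48 ± 0.11. Of 16 interferon response genes 8 fell (8 adjusted over the list alone; adjusted p = 0.00386), with Ifit1 at -0.85 ± 0.18 (both adjusted p = 0.416 with an estimated correlation).

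Further lists also moved between days 7 and 14, and whether these transcripts came from other cells was not tested. Of 21 fibrous matrix genes 17 fell (20 adjusted over the list alone; adjusted p = 1.70e-12), with Postn, periostin, at -4.81 ± 0.43 and Fn1 at -2.12 ± 0.26. Of 10 endothelial adhesion genes 5 fell and 1 rose (6 adjusted over the list alone; adjusted p = 0.00691), with Icam1 at -2.44 ± 0.13. Of 9 osteoclast genes 3 fell (4 adjusted over the list alone; adjusted p = 0.0172), with Ctsk at -2.45 ± 0.33. Of 14 lipid-associated macrophage genes 8 fell and 1 rose (9 adjusted over the list alone; adjusted p = 0.00256), with Apoe at -1.72 ± 0.16. Of 10 alternative activation genes 4 fell and 1 rose (8 adjusted over the list alone; adjusted p = 0.0154), with Socs3 at -0.69 ± 0.16, and of 8 B cell RNA genes 4 rose (5 adjusted over the list alone; adjusted p = 0.00107), with Cd79b at 1.14 ± 0.22. These 6 lists had adjusted p = 0.287 with an estimated correlation. Of 10 resident macrophage genes 4 fell and 1 rose (8 adjusted over the list alone; adjusted p = 0.0287, and adjusted p = 0.416 with an estimated correlation), with C1qb at -2.97 ± 0.48. Of 8 neutrophil RNA genes 2 fell (2 adjusted over the list alone; adjusted p = 0.0462, and adjusted p = 0.419 with an estimated correlation), with Retnlg at -0.83 ± 0.19. Of 8 mitochondrial transcripts 4 rose (6 adjusted over the list alone; adjusted p = 0.000492, and adjusted p = 0.357 with an estimated correlation), with mt-Nd2 at 0.66 ± 0.10. The other 9 lists were not called (adjusted p = 0.0802 to 0.635).

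Monocyte and macrophage-like cells were compared between grafted and sham femurs of the same day in the same way. Ctsk (ENSMUSG00000028111), the collagen-degrading cathepsin of osteoclasts, rose by 6.36 ± 0.49 (adjusted p = 0.000182; 6 grafted and 3 sham libraries), Spp1 by 4.24 ± 0.43 (adjusted p = 0.000525), Acp5, tartrate-resistant acid phosphatase, by 3.76 ± 0.64 (adjusted p = 0.00511), the matrix protease Mmp14 by 3.71 ± 0.38, the platelet factor Pf4 by 3.70 ± 0.58 and the chemokine Cxcl3 by 2.99 ± 0.42. Elane and Ctsg, granule proteases, fell (-0.99 ± 0.14 and -0.98 ± 0.15), as did Stxbp6 (-0.99 ± 0.16), Tnip3 (-0.98 ± 0.14) and the histone genes Hist1h2ae (-0.92 ± 0.10) and Hist1h2ap (-0.89 ± 0.26). Each moved in the same direction in 6 of 6 grafted libraries, as the naming rule required. In all, 2541 of 13907 genes passed, 1333 higher and 1208 lower. DESeq2 gave 1297 higher and 1501 lower and RLE factors 1246 and 1393, so the larger side depends on the scaling. The count was 1531 and 1032 without the sham library of day 1 or day 14, and 1647 and 1671 without replicate 1 of grafted day 1 or day 14. Clusters 11 and 12 held most of the class in sham libraries (43.0% and 43.0% on day 1, 23.2% and 64.4% on day 14), while cluster 22, led by Ctsk, Apoe and Acp5, held 31.9% and 31.0% of grafted day 1 cells. Within clusters 11 and 12 alone, 628 genes passed, with Ctsk at 1.88 (adjusted p = 0.0383), Spp1 at 1.35 (0.0123), Cxcl3 at 2.08 (0.01004) and Elane at -0.61 (0.0203), while Acp5 was at 0.46 (0.237) and Pf4 at 0.77 (0.335). In cluster 22 alone Ctsk (2.43, adjusted p = 0.0412), Spp1 (8.49, 0.000359), Cxcl3 (14.6, 0.000359), Pf4 (3.09, 0.00470) and Mmp14 (1.51, 0.0125) passed. Acp5 (0.39), Hist1h2ae (-1.70) and Hist1h2ap (-1.09) kept their sign there and did not pass. Elane (0.29), Tnip3 (1.05) and Stxbp6 (8.03) had the opposite sign and did not pass. Cluster 22 was at 0.571%, 0.403% and 0.165% of cells in the sham libraries of days 1, 7 and 14. The last fell short of 20 cells and was left out, so few sham cells stand behind these values.

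Of 13 osteoclast genes 12 rose in grafted libraries (12 adjusted over the list alone), with Tnfrsf11a, which encodes the receptor RANK, at 1.41 ± 0.13, the fusion gene Dcstamp at 3.71 ± 0.39 and Car2 at 2.47 ± 0.39 (camera adjusted p = 1.11e-06). Within clusters 11 and 12 and within cluster 22, Tnfrsf11a was at 0.41 (adjusted p = 0.133) and 0.36 (0.502), and Car2 at -0.20 (0.771) and 0.15 (0.892). In cluster 22 Dcstamp was at 0.69 (0.515) and Acp5 at 0.39 (0.542), while Ctsk passed there at 2.43 (0.0412). Of 14 lipid-associated macrophage genes 9 rose (12 adjusted over the list alone), with Gpnmb at 3.88 ± 0.50, the scavenger receptor Cd36 at 2.24 ± 0.20 and the lipid droplet coat gene Plin2 at 0.63 ± 0.08 (adjusted p = 1.37e-05). Of 12 alternative activation genes 6 rose (8 adjusted over the list alone), with Arg1, arginase, at 7.19 ± 0.57, the elastase Mmp12 at 3.67 ± 0.37 and Il4ra at 0.68 ± 0.12 (adjusted p = 0.0287). Arg1, Plin2 and Il4ra passed within clusters 11 and 12 and within cluster 22, while Gpnmb was at 1.45 (adjusted p = 0.0542) and 2.39 (0.212) and Mmp12 at 2.23 (0.132) and 9.95 (0.156) there. Of 10 primary granule genes 6 fell (8 adjusted over the list alone), with Prtn3 at -0.85 ± 0.13 and Serpinb1a at -0.70 ± 0.10 (adjusted p = 7.71e-05). Of 15 secondary and tertiary granule genes 4 fell and 1 rose (6 adjusted over the list alone), with Hp at -0.67 ± 0.14 (adjusted p = 0.00278). Of 11 osteoblast genes 6 rose (8 adjusted over the list alone; adjusted p = 0.000982), with Runx2 at 0.86 ± 0.16. Of 17 fibrous matrix genes 8 rose (10 adjusted over the list alone; adjusted p = 0.00235). Free RNA held more of the 15 fibrous matrix genes higher in grafted than sham neutrophil-like cells, while osteoblast genes were not counted in it. In barcodes with 100 UMIs or fewer those 15 genes stood at 2296 and 946 CPM in the grafted libraries of day 7. They stood at 250 CPM in the sham library of that day, and their part in monocyte and macrophage-like cells was not tested. These 7 lists had adjusted p = 0.435 with an estimated correlation. Of 23 cell cycle genes 12 fell (22 adjusted over the list alone; adjusted p = 5.02e-08), with Tyms at -0.72 ± 0.10, Stmn1 at -0.70 ± 0.13 and Hmgb2 at -0.65 ± 0.10. Of 18 dissociation and immediate early genes 4 fell and 1 rose (12 adjusted over the list alone; adjusted p = 0.00807), with Klf2 at -0.80 ± 0.13 and Nr4a1 at -0.75 ± 0.09 (both adjusted p = 0.449 with an estimated correlation). Within clusters 11 and 12 Klf2 and Nr4a1 passed (-1.02 and -0.65). In cluster 22 they were at -0.22 (adjusted p = 0.740) and 0.41 (0.415). Of 16 resident macrophage genes 3 rose (4 adjusted over the list alone; adjusted p = 0.00246), the mannose receptor Mrc1 at 1.22 ± 0.37, Maf at 0.73 ± 0.19 and Adgre1 at 0.48 ± 0.09. None of these 3 passed within clusters, where Mrc1 was at -0.24 (clusters 11 and 12) and -0.68 (cluster 22), Maf at 0.30 and -0.66, and Adgre1 at 0.31 and 0.13. Markers of RNA from other cells and of RNA quality were called too: 1 of 8 neutrophil RNA genes fell, Retnlg at -1.07 ± 0.24 (1 adjusted over the list alone; adjusted p = 0.0287), and none of 7 erythroid genes passed while their median stood at 1.29 (adjusted p = 0.0407). Of 8 mitochondrial transcripts 1 rose, mt-Nd1 at 0.41 ± 0.10 (1 adjusted over the list alone; adjusted p = 0.0267). These 4 lists had adjusted p = 0.525 with an estimated correlation. The other 12 lists were not called (adjusted p = 0.0534 to 0.835), among them the inflammatory list, with 4 of 20 higher and 1 lower.

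**Figure D4:**
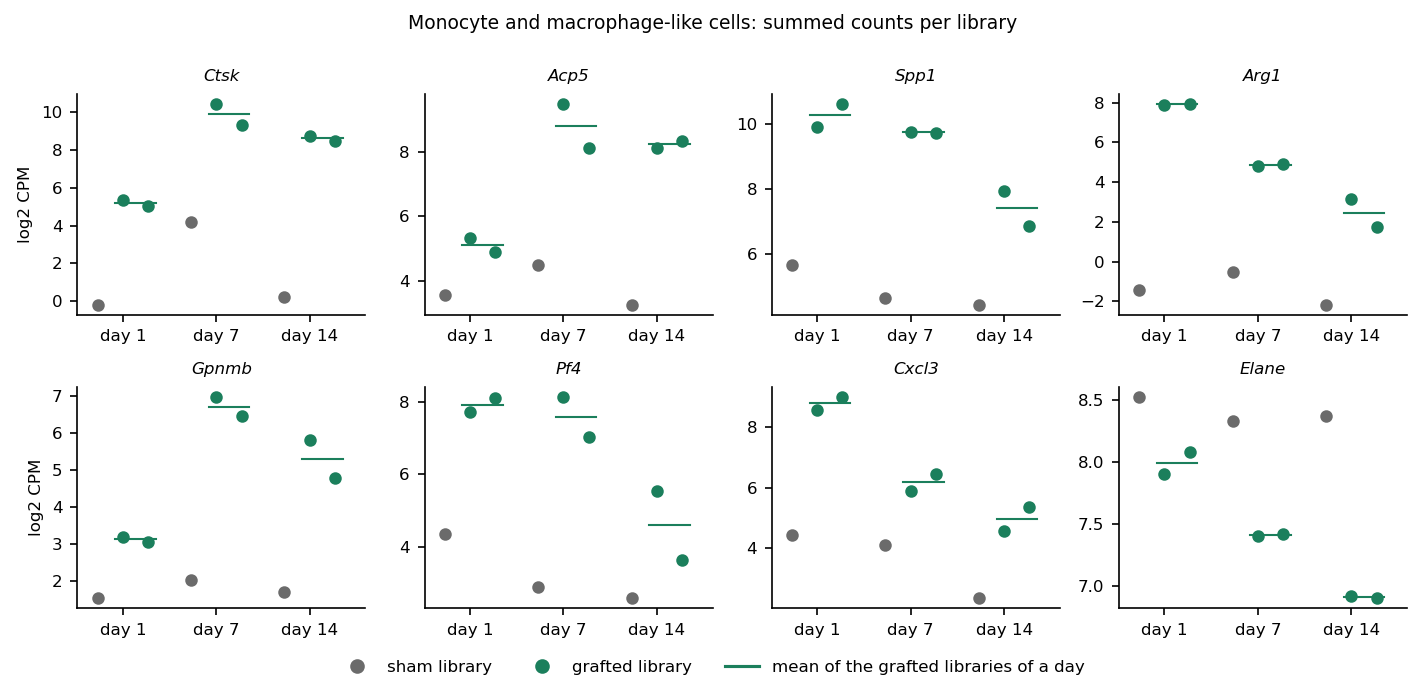
Log2 CPM of 8 genes in monocyte and macrophage-like cells (y axis, one panel per gene) against day, with 1 point per library for sham and grafted femurs. Ctsk, Acp5, Spp1, Arg1, Gpnmb, Pf4 and Cxcl3 lie higher and Elane lower in all 6 grafted libraries than in the sham library of their day, and the mean difference of Ctsk was 5.38, 5.67 and 8.36 on days 1, 7 and 14.

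For no gene in these cells did the graft effect differ between days by edgeR (0 at an adjusted p of 0.05, 1671 of 13907 at an unadjusted p under 0.05), while DESeq2 called 151 and edgeR without a filter on low counts 981.

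From day 1 to day 7 after grafting, 11 of 13 osteoclast genes rose in monocyte and macrophage-like cells. Ctsk rose by 4.75 ± 0.37 (adjusted p = 0.00159; 2 and 2 libraries), Acp5 by 3.83 ± 0.43, the gelatinase Mmp9 by 3.67 ± 0.44, Ckb by 3.05 ± 0.46, Timp2 by 2.74 ± 0.44 and Apoe by 2.43 ± 0.18. Cxcl3 (-2.60 ± 0.29), Dmkn (-2.11 ± 0.25), Wfdc21 (-2.03 ± 0.39), Phgdh, an enzyme of serine synthesis (-1.77 ± 0.18), Ifitm1 (-1.73 ± 0.17) and Tcf7l2 (-1.54 ± 0.19) fell. In all, 2086 genes passed, 1059 higher and 1027 lower, and 88.6% of these differed in the same direction between the sham libraries of these days. The median ratio of the sham to the grafted difference was 0.837, so changes of similar size were seen without a graft. The count was 453 and 54 without grafted day 1 replicate 1 or 2, and 1014 without grafted day 7 replicate 1. Cluster 12 held 39.8% and 53.7% of the class in the grafted day 7 replicates and cluster 22 28.9% and 16.3%. On day 14 clusters 12 and 13 held 55.7% and 21.3% in replicate 1 and 47.9% and 32.0% in replicate 2. Of all cells that were not erythroid-like, cluster 22 held 3.38% ± 1.50 (SD, n = 2) in grafted libraries on day 7. On day 14 it held 0.844% ± 0.112, and its part in the day 14 contrast was not tested.

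Of 13 osteoclast genes 11 rose from day 1 to day 7 (13 adjusted over the list alone; camera adjusted p = 2.11e-07), with Atp6v0d2, a proton pump subunit, at 5.09 ± 0.42. Of 23 cell cycle genes 18 fell (19 adjusted over the list alone; adjusted p = 1.02e-08), with Mcm5 at -0.95 ± 0.12 and Ccnb1 at -0.90 ± 0.13. Of 17 fibrous matrix genes 8 rose and 4 fell (14 adjusted over the list alone; adjusted p = 0.0149), with Mmp13 at -2.72 ± 0.30 and Timp1 at -1.85 ± 0.13. These 3 lists had adjusted p = 0.520 with an estimated correlation. The test of the fibrous matrix list turned to lower without grafted day 7 replicate 1 (median log2 difference 0.04) or replicate 2 (-0.16). Of 17 interferon response genes 10 rose (13 adjusted over the list alone; adjusted p = 9.38e-06, and adjusted p = 0.598 with an estimated correlation), with Ifi27l2a at 1.71 ± 0.17, Xaf1 at 1.46 ± 0.21 and the transcription factor Irf7 at 1.43 ± 0.22. Of 18 dissociation and immediate early genes 11 rose (15 adjusted over the list alone; adjusted p = 2.11e-07, and adjusted p = 0.229 with an estimated correlation), with Atf3 at 1.93 ± 0.15 and Fos at 1.85 ± 0.13. Of 18 hypoxia and glycolysis genes 10 fell and 2 rose (13 adjusted over the list alone; adjusted p = 0.00138), with Pgk1 at -0.84 ± 0.09 and Hk2 at 1.13 ± 0.10. Of 10 primary granule genes 7 fell (8 adjusted over the list alone; adjusted p = 7.39e-05), with Ms4a3 at -2.51 ± 0.12 (both adjusted p = 0.260 with an estimated correlation). Of 11 class II antigen presentation genes 4 rose (8 adjusted over the list alone; adjusted p = 0.000637), with Cd74 at 1.25 ± 0.32. None of 7 erythroid genes passed over all genes (6 adjusted over the list alone, median -1.88; adjusted p = 0.0145); both had adjusted p = 0.609 with an estimated correlation. Of 14 lipid-associated macrophage genes 6 rose (7 adjusted over the list alone), with Gpnmb at 3.63 ± 0.35. Of 8 mitochondrial transcripts 2 rose (3 adjusted over the list alone), with mt-Nd2 at 0.71 ± 0.15 (both adjusted p = 0.0149, and adjusted p = 0.759 with an estimated correlation). Of 9 angiogenic genes 4 rose (6 adjusted over the list alone; adjusted p = 0.0123, and adjusted p = 0.361 with an estimated correlation), with Pgf at 1.69 ± 0.35. Of 5 skeletal muscle genes 1 rose, Tnnt3 at 1.76 ± 0.34 (1 adjusted over the list alone; adjusted p = 0.0238, and adjusted p = 0.419 with an estimated correlation).

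From day 7 to day 14, 9 of 20 inflammatory and 9 of 14 lipid-associated genes fell in monocyte and macrophage-like cells. Saa3, an acute phase protein, fell (-3.46 ± 0.38, adjusted p = 0.00935), as did Pf4 (-2.81 ± 0.58), the neutrophil chemokine Cxcl1 (-2.54 ± 0.39), Spp1 (-2.24 ± 0.34), G0s2 (-2.04 ± 0.22) and Wfdc21 (-1.85 ± 0.40). Hdac9 rose by 1.32 ± 0.16, Arrdc3 by 1.29 ± 0.10, Bach2 by 1.23 ± 0.15, Stxbp6 by 1.19 ± 0.09, Fyn by 1.14 ± 0.15 and Grk5 by 1.14 ± 0.15. In all, 1250 genes passed, 730 higher and 520 lower (58.4% higher). DESeq2 gave 533 higher and 599 lower (47.1% higher), and 57.0% of the 1250 differed in the same direction between the sham libraries. The count was 144 and 157 without grafted day 1 replicate 1 or 2, 82 without day 7 replicate 1, and 182 and 53 without day 14 replicate 1 or 2.

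Of 20 inflammatory genes 9 fell from day 7 to day 14 (13 adjusted over the list alone; camera adjusted p = 5.91e-05), with Ccl8 at -2.69 ± 0.40 and Il1rn at -1.35 ± 0.23. Of 14 lipid-associated genes 9 fell (11 adjusted over the list alone; adjusted p = 0.000304), with Ctsl at -1.41 ± 0.09 and Apoe at -1.21 ± 0.17. Of 8 neutrophil RNA genes 3 fell (4 adjusted over the list alone; adjusted p = 0.000821), with S100a8 at -1.96 ± 0.31, and of 8 B cell RNA genes 2 rose (7 adjusted over the list alone; adjusted p = 0.000864), with Ebf1 at 2.62 ± 0.32. These 4 lists had adjusted p = 0.590 with an estimated correlation. Of 18 hypoxia and glycolysis genes 10 fell (13 adjusted over the list alone; adjusted p = 2.03e-06, and adjusted p = 0.254 with an estimated correlation), with Bnip3 at -1.04 ± 0.12, Hk2 at -1.03 ± 0.10 and Aldoa at -0.68 ± 0.09. Of 17 fibrous matrix genes 6 fell (12 adjusted over the list alone; adjusted p = 5.91e-05), with Mmp14 at -1.62 ± 0.31. Of 10 primary granule genes 3 fell (5 adjusted over the list alone; adjusted p = 0.00606), with Elane at -0.50 ± 0.09 (both adjusted p = 0.489 with an estimated correlation). Of 23 cell cycle genes 4 fell (10 adjusted over the list alone; adjusted p = 9.38e-05, and adjusted p = 0.658 with an estimated correlation), with Plk1 at -0.67 ± 0.14. Of 13 osteoclast genes 1 fell, Ctsk at -1.36 ± 0.32 (2 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.733 with an estimated correlation). Of 11 class II genes 1 rose, Cd86 at 0.80 ± 0.09 (1 adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.672 with an estimated correlation). Of 15 secondary and tertiary granule genes 1 fell, Retnlg at -2.76 ± 0.22 (4 adjusted over the list alone; adjusted p = 0.0449, and adjusted p = 0.688 with an estimated correlation). None of 7 erythroid genes passed (median 1.37; adjusted p = 0.0313, and adjusted p = 0.661 with an estimated correlation). Without grafted day 7 replicate 2, 7 lists were called in place of 12.

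Mesenchymal-like cells could be compared between day 7 (240 and 107 cells) and day 14 (21 cells in replicate 2) only, so day 14 rested on 1 library assumed to vary like those of day 7, with 1 residual degree of freedom. Cfh, a complement regulator, rose by 3.89 ± 0.66 (adjusted p = 0.0117), Satb2, a transcription factor of osteoblasts, by 3.53 ± 0.54 (adjusted p = 0.00757), Nupr1 by 3.39 ± 0.33, Ckb by 3.32 ± 0.28, Fam180a by 3.21 ± 0.34 and Kcnq5 by 3.01 ± 0.23. The monocyte chemokines Ccl2 and Ccl7 fell (-4.50 ± 0.37 and -4.45 ± 0.47), as did the Wnt antagonist Sfrp1 (-4.33 ± 0.34) and Il1r1 (-4.12 ± 0.39), and the histone gene Hist1h2ap and Wfdc21, which also fell, had 1 and 2 counts on day 14 against 2715 and 2485 on day 7. In all, 1035 of 12563 genes passed, 517 higher and 518 lower. Doublets kept gave 130 genes, DESeq2 460, and a minimum of 15 cells, which added day 14 replicate 1, 424. Of 32 named genes measured in each of these settings, 12 lost their call with that minimum and 21 with doublets kept. Cluster 29, of low UMI counts, held 51.4% of day 7 replicate 2, cluster 30 held 120 of the 240 cells of day 7 replicate 1, and clusters 25 and 31 held 38.1% and 33.3% of day 14 replicate 2.

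Of 17 osteoblast genes 9 rose in mesenchymal-like cells (12 adjusted over the list alone; camera adjusted p = 3.36e-06), with Phex, a regulator of mineralization, at 4.54 ± 0.38, Sparc at 1.72 ± 0.22 and Col1a1, the main collagen of bone, at 1.52 ± 0.21. Of 14 marrow stromal niche genes 6 fell and 1 rose (10 adjusted over the list alone; adjusted p = 0.00513), with the chemokine Cxcl12 at -3.07 ± 0.43 and Igfbp5 at 2.76 ± 0.25. Of 19 inflammatory genes 8 fell (15 adjusted over the list alone; adjusted p = 2.52e-08), with Ptgs2 at -2.54 ± 0.37. Of 10 endothelial adhesion genes 5 fell (5 adjusted over the list alone; adjusted p = 6.12e-05), with Vcam1 at -2.89 ± 0.36. Of 23 cell cycle genes 21 fell (23 adjusted over the list alone; adjusted p = 8.68e-17), with Hmgb2 at -3.07 ± 0.30. These 5 lists had adjusted p = 0.734 with an estimated correlation. Of 16 cartilage genes 6 rose (8 adjusted over the list alone; adjusted p = 0.00513), with Comp at 2.48 ± 0.41, Sox6 at 2.41 ± 0.24 and Cnmd at 2.01 ± 0.32. None of 19 hypoxia genes passed over all genes (7 adjusted over the list alone; adjusted p = 0.0107); both had adjusted p = 0.832 with an estimated correlation. RNA of other cells moved with these groups: 8 of 8 neutrophil RNA genes fell (8 adjusted over the list alone; adjusted p = 1.27e-06), with S100a8 at -5.73 ± 0.49, 8 of 15 secondary and tertiary granule genes (10 adjusted over the list alone; adjusted p = 1.93e-06), 5 of 16 mature neutrophil genes (11 adjusted over the list alone; adjusted p = 1.49e-05) and 1 of 7 primary granule genes fell (1 adjusted over the list alone; adjusted p = 0.00510), and 4 of 6 B cell RNA genes rose (4 adjusted over the list alone; adjusted p = 0.00117), with Vpreb3 at 4.19 ± 0.52. These 5 lists had adjusted p = 0.734 with an estimated correlation.

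Endothelial-like cells were compared between day 14 (23 and 24 cells) and day 7 (37 cells in replicate 1), all from cluster 28, with day 7 on 1 library and 1 residual degree of freedom. The 12 genes named next all lost their call with RLE factors and with doublets kept. Robo1 (ENSMUSG00000022883), a guidance receptor, rose by 3.59 ± 0.48 (adjusted p = 0.0400), the chaperone Hspa1b by 3.55 ± 0.53, Clic5, a marker of capillary cells, by 3.18 ± 0.48, Rapgef4 by 1.90 ± 0.30, Igfbp3 by 1.51 ± 0.21 and Flt1, a receptor for VEGF, by 1.22 ± 0.19. Tgfbi (-3.22 ± 0.37), Il1r1, the interleukin 1 receptor (-2.84 ± 0.39), Vwf (-2.42 ± 0.32), the adhesion molecule Selp (-2.18 ± 0.30), Mest (-1.78 ± 0.27) and Lrg1 (-1.63 ± 0.25) fell. In all, 49 of 8936 genes passed, 7 higher and 42 lower (14.3% higher). DESeq2 gave 33 higher and 79 lower (29.5% higher), while RLE factors and doublets kept each gave 0. Of 12 endothelial adhesion genes 4 fell (6 adjusted over the list alone; camera adjusted p = 0.00551), Vwf, Selp and Lrg1 among them. Of 10 inflammatory genes 1 fell (3 adjusted over the list alone; adjusted p = 0.000604). Of 18 dissociation and immediate early genes 1 rose, Hspa1b (6 adjusted over the list alone; adjusted p = 0.00232). No member passed over all genes in 5 further called lists: lower on day 14 were fibrous matrix (3 of 17 adjusted over the list alone; adjusted p = 0.000604) and mature neutrophil genes (1 of 12; adjusted p = 0.0160), and higher were marrow stromal niche (0 of 13; adjusted p = 0.00817), resident macrophage (2 of 6; adjusted p = 0.00884) and class II genes (5 of 6; adjusted p = 0.00186). These 8 lists had adjusted p = 0.831 with an estimated correlation.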

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

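The tests of EGFP and of other splits of the libraries were chosen only after their results had been seen, while those of matrix genes and of cluster 27 were chosen before.

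A difference between groups was noted for 81 genes in neutrophil-like cells, whose graft effect differed between days by edgeR, led by Tnf, Ccl3 and Tnfaip3. T and NK-like cells differed between grafted and sham libraries by 2.05 percentage points on day 14, where both grafted libraries lay higher, and by -3.37 on day 1 and -1.05 on day 7, where both lay lower. Cluster 21 differed by 2.46 points on day 14, -5.85 on day 1 and -2.42 on day 7 in the same way. Neutrophil-like cells differed by 4.20 points on day 1 and by -8.65 on day 14. Single libraries decide some of these sizes: on day 14, T and NK-like cells were at 4.40% and 6.83% in the grafted replicates against 3.56% in the sham library, and neutrophil-like cells at 49.1% and 33.8% against 50.1%, and on day 1 neutrophil-like cells were at 54.1% and 50.3% against 48.0%. These differences of shares between days were not tested.

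EGFP in neutrophil-like cells of day 1 was weighed against free EGFP RNA and against shallower libraries on day 14. At equal depth the share of neutrophil-like cells with EGFP was 28.0 times that of B cell-like cells on day 1, over the 5 times above which free RNA was ruled out as the whole cause. The share on day 14, pooled over replicates, was 0.0496 of that on day 1 at equal depth, which depth alone does not give. The day 14 cells with EGFP were 12 of 3183 in replicate 1 and 0 of 2292 in replicate 2. Free RNA held about as much EGFP per UMI as cells did (21.5 and 16.5 against 20.6 and 17.4 CPM in the day 1 replicates), so it may add to these shares. Both predictions were written after the shares had been seen, so they can only exclude. Neutrophils that came with the graft and were lost later could give this pattern, and no test of survival was possible.

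Matrix genes in neutrophil-like cells of grafted libraries were weighed against free RNA from mesenchymal cells, doublets, and transcription in neutrophils. They were counted as the 15 fibrous matrix genes that rose there, without osteoblast and cartilage genes. On day 7 the lower of B cell-like and T and NK-like cells held 1.09 times the matrix UMIs per cell of neutrophil-like cells, which is what free RNA would give. Only 3.54% of the matrix UMIs of neutrophil-like cells lay in cells with 5 or more, against the prediction for doublets, and neutrophil-like cells held 0.594 times those of B cell-like cells, against transcription in neutrophils. The rise of these 15 genes in neutrophil-like cells on day 7 is therefore likely free RNA, while osteoblast and cartilage genes were not weighed. Days 1 and 14 were not weighed. Per 100 cells, neutrophil-like cells held 0.892 UMIs in the day 1 sham library and 2.79 and 3.58 in the grafted ones. T and NK-like cells held 2.61, and 0.935 and 2.29, on at most 6 UMIs. On day 14 these were 1.28, 5.79 and 8.92 in neutrophil-like and 2.06, 8.33 and 9.01 in T and NK-like cells. B cell-like cells held 6.03 and 9.56 in those sham libraries, above neutrophil-like cells, which limits the ratio of 0.594. Whether free RNA came from cells of the graft or of the host was not tested.

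Cluster 27, seen in grafted libraries only, was weighed against genomic DNA counted over long genes and droplets of free RNA. UMIs per gene correlated with gene span at a Spearman rho of 0.888 in cluster 27 and at 0.159 in the highest other cluster, as genomic DNA would give. Its share of UMIs in the 50 genes with the most free RNA was 0.0704 of that in free RNA, against droplets of free RNA. Unspliced nuclear RNA also follows gene span and was not tested separately, and no biological explanation was tested.

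Of the 81 splits of the 9 libraries into 6 and 3 that can be fitted beside day, 27 of them within days, 1 gave as many genes as grafted against sham in each class. That was the real grouping, with 2768 genes in neutrophil-like cells (3 in the highest other split) and 2541 in monocyte and macrophage-like cells (0 in the highest other split).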

How the results depend on the processing

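The alternatives without cells of EGFP or of single clusters, within single clusters, with a minimum of 15 cells, and with cluster 21 or 13 counted in another class were added after seeing the data, and the cause of a change was not tested unless cells or libraries were left out by construction. For named genes, 268 calls stayed and 8 were lost with DESeq2, 272 and 12 with RLE factors, 284 and 0 at 1000 UMIs, 282 and 2 at resolution 2, 242 and 41 with doublets kept, 284 and 1 without a filter on low counts, and 1953 and 192 without each library in turn, and none reversed. No result was ended or turned among those run, which were 23 at 1000 UMIs and 20 without cells holding EGFP (shares, gene counts and, for the latter, numbers of lists called), 13, 13, 9 and 12 shares at a mitochondrial maximum of 5%, with all retained cells as denominator, at resolution 0.5 and without cluster 27, and 4 gene counts without cluster 26 and 1 without cluster 29. None of these shares had passed the correction in the main test, so they could not be ended, and only their unchanged sign is shown. DESeq2 gave 112 genes in endothelial-like and 460 in mesenchymal-like cells, and 199 and 151 whose graft effect differs between days in neutrophil-like and in monocyte and macrophage-like cells. RLE factors gave 0 in endothelial-like cells and resolution 2 gave 103. Doublets kept gave 0 and 130 in endothelial-like and mesenchymal-like cells, and a minimum of 15 cells 424 in the latter. Without a filter on low counts, counts were 555 (endothelial-like), 2126 (mesenchymal-like), 3374 and 2962 (monocyte and macrophage-like, day 7 against 1 and day 14 against 7), and 611 and 981 for the graft effect between days in neutrophil-like and monocyte and macrophage-like cells. In monocyte and macrophage-like cells, grafted against sham gave 628 genes in clusters 11 and 12, 542 in cluster 22 and 9 in cluster 13, day 7 against day 1 gave 3379 in clusters 11 and 12 and 18 in cluster 13, day 14 against day 7 gave 2015, 185 and 87, and the graft effect between days 11 in clusters 11 and 12 and 2 in cluster 22. By edgeR on cell numbers, log2 differences were 0.82 (B cell-like), 8.69 (cluster 27), -0.95 (dendritic-like), 1.93 (endothelial-like) and -0.74 (granulocyte-monocyte progenitor-like), all past the threshold. With cluster 21 counted as B cell-like, these were 0.23 (B cell-like, adjusted p = 0.253), 1.95 (endothelial-like), -0.95 (dendritic-like) and 3.77 (mesenchymal-like, past the threshold). With cluster 13 counted as dendritic-like they were -0.29 (dendritic-like, adjusted p = 0.312), 0.82 (B cell-like) and 1.92 (endothelial-like), and monocyte and macrophage-like cells turned to -0.0639 (-0.0669 by the exact test). With an estimated correlation 0 gene lists were called in any comparison, against 8 to 16. The labels do not say that the replicate numbers pair the samples, and the r values given next were not tested. Across genes, the difference of grafted replicate 1 from replicate 2 was correlated between days. For days 1 and 7, 1 and 14, and 7 and 14, r was -0.353, 0.0488 and -0.227 in neutrophil-like cells. It was 0.190, 0.0432 and 0.173 in monocyte and macrophage-like cells. A fit with a replicate block gave 983 genes for grafted against sham in neutrophil-like cells. It gave 46 for the graft effect between days in monocyte and macrophage-like cells. Leaving out each library in turn gave 1630 to 2520 genes (neutrophil-like, grafted against sham), 414 to 2539 (day 14 against 7) and 2 to 251 (graft effect between days), and 1032 to 2549, 54 to 2075 (day 7 against 1), 53 to 1577 and 0 to 4 in monocyte and macrophage-like cells, with 7 to 13 lists for day 14 against 7. The fibrous matrix list, day 7 against day 1 in these cells, ran from -0.16 to 1.91 (0.04 without grafted day 7 replicate 1, -0.16 without replicate 2). Shares ran from -0.80 to 0.07 for T and NK-like cells (0.0715 without the sham library of day 1), -1.22 to 0.04 for cluster 21 (0.0392 without that of day 7) and -0.30 to 0.08 for neutrophil-like cells (0.0784 without that of day 14, 0.03 without grafted day 14 replicate 2), and for EGFP from 6.41 to 8.26, where fewer arrangements keep the exact p above 0.05. A lone library was assumed to vary like the other groups. Leaving out libraries and the replicate block were not run in mesenchymal-like and endothelial-like cells, where no degrees of freedom would remain. Depth limits the detection of EGFP, since a cell of 2000 UMIs may hold none.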

Other observations

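Neutrophil-like cells with and without EGFP were compared within the 4 grafted libraries of days 1 and 7. By edgeR 0 of 13645 genes passed, while 2430 had an unadjusted p under 0.05, and 156 passed without grafted day 7 replicate 2. Hypoxia and glycolysis genes were higher in cells with EGFP (median log2 difference 0.75 over 18 genes, camera adjusted p = 1.54e-08, and adjusted p = 0.786 with an estimated correlation). Cell cycle genes were lower (-1.05 over 23 genes, adjusted p = 6.42e-08), as were secondary and tertiary granule genes (-0.88, adjusted p = 0.00105), primary granule genes (-0.88, adjusted p = 0.0274), neutrophil RNA genes (-0.86, adjusted p = 0.0181), erythroid RNA (-0.62, adjusted p = 0.0181) and mitochondrial transcripts (-0.68, adjusted p = 0.0274), all with adjusted p = 0.786 with an estimated correlation. No member of these 7 lists passed alone. Cells with and without EGFP lay in different clusters: on day 1 cluster 26 held 149 of the 396 cells with EGFP and cluster 2 held 28, while these held 1.80% and 2.68%, and 37.2% and 39.2%, of all neutrophil-like cells of the replicates. Without grafted day 1 replicate 1 or 2, the lists of primary granules (adjusted p = 0.164 and 0.161), neutrophil RNA (0.119 and 0.169) and mitochondrial transcripts (0.184 and 0.187) were not called, and erythroid RNA was not called without replicate 2 (0.223). Primary granules were not called without grafted day 7 replicate 1 either (0.0626). Without cluster 26 the hypoxia list was at 0.67 (adjusted p = 2.00e-09, and adjusted p = 0.716 with an estimated correlation), and primary granules (0.108) and mitochondrial transcripts (0.0573) were not called. Without it 3 genes passed, and with EGFP at 3 UMIs or more 2 did. This comparison was chosen after the EGFP shares had been seen.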
